A study of Caenorhabditis elegans with 2 samples.

How the data were processed

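ChIP-seq of CEH-2-GFP was made from whole hermaphrodite late embryos of strain OP323, in 2 biological replicates per the labels, which name 1 group and no second one. The labels describe sonicated chromatin, an antibody against GFP and a C-terminal GFP-FLAG tag. Per the file headers, the authors called a relaxed peak list on each replicate's alignments with a control, another on the alignments of both replicates with a control, and derived the optimal set from these lists by the irreproducible discovery rate (IDR). Coordinates are on ce11 and ce10 per the labels. The peak caller, its version, the aligner, the filters and the IDR threshold are not given in the sources used here. The control itself was not analysed here.

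The deposited signal value of a peak is the authors' peak caller's own measure, on a scale that is not given, and it was used only to rank, filter and describe peaks within a list. Pooled and single-replicate signals are on different scales and were not subtracted from each other. The deposited −log10 q-value of the reproducible peaks ran from 2.31 to 2.88 and was tied among the strongest peaks, so it was not used to rank them. The reproducible set was identical to the pooled list at or above a signal of 86.3, for 1453 of 1453 peaks. No read counts are in the lists, so the depth and any floor that needs it are unknown, and intervals cover the counting of peaks or genes only.

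Gene models came from Ensembl release 115 for WBcel235, the same assembly as ce11, and sequence from the RefSeq genome of that assembly. The highest end of the pooled peaks lay within each chromosome. The ce10 lists were used for counts and for overlap within ce10, and no coordinate was converted. Positions are 1-based. A promoter window ran from 1000 bp upstream to 200 bp downstream of each transcript start of a protein-coding gene. A summit in the windows of several genes was given to each of them.

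Replicate overlap took the 1453 strongest peaks of each replicate and counted those of replicate 1 that shared 1 bp with one of replicate 2. The design did not foresee mitochondrial peaks. After they were seen, they were left out, which gave 1435 and 1429 peaks here and 1430 reproducible peaks everywhere else. Expected values came from 10000 circular shifts of the peaks within each chromosome. The rank correlation has a bootstrap interval from 1000 resamples of peaks and no p-value. Gene groups were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 18 groups, and odds ratios have 0.5 added to each cell. Chromosome shares were tested by exact binomial tests adjusted over 6 chromosomes, and the medians of signal by a permutation test with 100000 resamples. Sequence tests compared windows within 50 bp of the summit with windows 300 bp to either side by exact McNemar tests, and the scan of 6-mers used the larger p of both sides.

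The gene groups, the tests of the main results, their settings chosen in advance and the rule for named genes were fixed before the data were examined. The settings without tRNA, snoRNA and snRNA loci, with mitochondrial peaks and with GC strata, and the tests named as such in the closing section, were added after the main results, the strongest peaks and the ceh-2 and unc-119 loci had been looked at. Named genes are those in the first 15 places when each gene is ranked by its highest promoter summit, with genes that share a summit in 1 place, ceh-2 and unc-119, and up to 4 members per group with the highest signal. All members of the 3 pharyngeal groups are given as counts. Alternatives were a stricter set of the strongest peaks, each replicate alone, other overlap rules, windows of 500 and 2000 bp, other backgrounds, other sequence windows and ce10. The position test of the gene groups first used a corrected odds ratio, which for a group with no hit depends on the total number of genes hit. It was replaced after its output was seen by the share of members over the share of all genes.

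The tests were tested on simulated data. A planted gene group, the 140 neuropeptide genes at a weight of 8, was called in 20 of 20 simulated peak sets over 19973 genes. With nothing planted, 2 of 360 tests of groups were called. The power for smaller groups or weaker effects was not simulated. A planted core ranked 1 of 2080 6-mers, and 0 6-mers were called with nothing planted. The simulated summits and flanks had the same base composition, unlike the real ones, so calls that come from GC content were not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.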

Results

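CEH-2 is a homeodomain protein of the EMX and empty spiracles family, whose members bind DNA at TAAT cores. Chromatin from whole late embryos of Caenorhabditis elegans strain OP323, which carries a CEH-2-GFP fusion, was immunoprecipitated with an antibody against GFP and sequenced. The worms were collected 5 hours after synchronization by egg bleaching. There was 1 group of 2 biological replicates. The relaxed list of replicate 1 held 18431 peaks, that of replicate 2 held 15188 and the list from pooled reads held 16046. The authors' optimal set under the irreproducible discovery rate, called the reproducible peaks here, held 1453 peaks, 9.06% of the pooled list. Of these, 1430 lay on the nuclear chromosomes and 23 on the mitochondrial genome. The peak lists give no read counts, so the depth of each replicate is unknown. All positions are on ce11.

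The first comparison asked how far the replicates found the same regions. The strongest nuclear region in both was upstream of K12H4.5 on chromosome III, 8043721 to 8044210, with a signal of 764 in replicate 1 and 988 in replicate 2. The second by pooled signal, near M01F1.9, had 591 and 643. Of the 1435 nuclear peaks among the strongest of replicate 1, 1060 overlapped one of the 1429 of replicate 2, or 73.9%. Shifted positions gave 1.24% on average (p = 0.0001, the smallest that 10000 permutations by circular shift can give, one-sided). Each reproducible peak was given the signal of the strongest overlapping peak of each replicate. Neighbouring reproducible peaks could therefore share the same values and count more than once. Over the 1428 reproducible peaks matched in both lists, Spearman's rho between the replicates' signals was 0.723 (95% bootstrap interval 0.694 to 0.753). With summits matched within 100 bp instead, rho was 0.712 over 1355 peaks. These correlations are across peaks, which are not independent replicates.

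**Figure D1:**
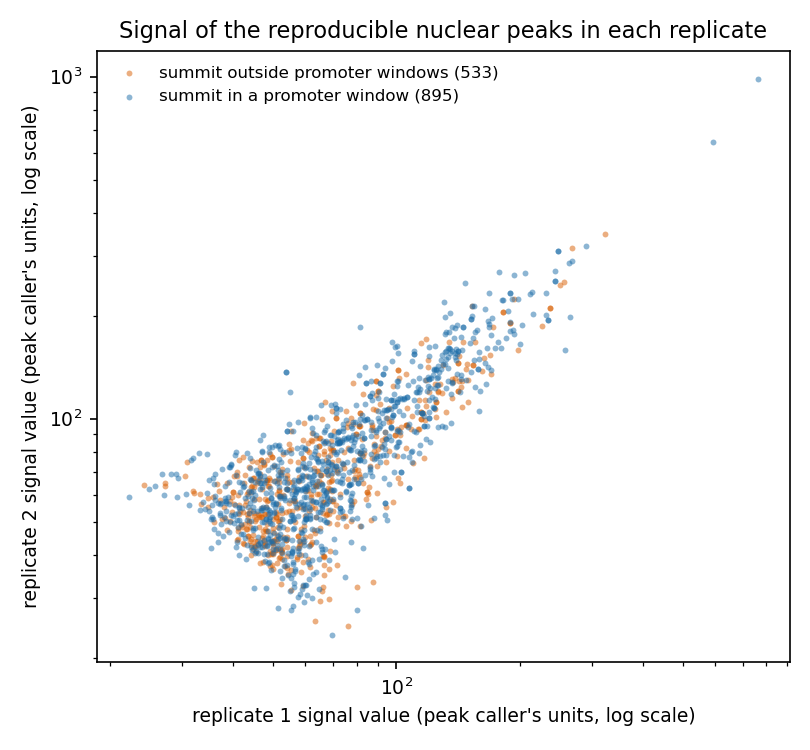
Signal value of the strongest replicate peak that overlaps each reproducible nuclear peak, in the peak caller's units, for the 1428 peaks matched in both. Replicate 1 is horizontal and replicate 2 vertical, both on log scales. Neighbouring reproducible peaks can share the same pair of values. Blue points have their summit in a promoter window and orange points do not; the signals rose together, with a rho of 0.723.

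The second comparison asked where the reproducible peaks lay relative to genes. Promoter windows of protein-coding genes, from 1000 bp upstream to 200 bp downstream of a transcript start, held 896 of the 1430 summits, or 62.7% (95% Wilson interval 60.1 to 65.1). Shifted positions gave 25.7% (two-sided p = 0.0002, the smallest that 10000 permutations by circular shift can give), and relaxed peaks outside the reproducible set gave 35.1%. By annotated feature of protein-coding genes alone, 71.3% of summits were intergenic, 23.2% were in introns and 3.50% were in 5′ UTRs. Noncoding genes were not used for these classes, so a summit in a noncoding gene could count as intergenic. Coding exons held 1.26% of the reproducible summits and 22.5% of the relaxed ones. The median signal was 131.6 in promoter windows and 118.8 elsewhere, a difference of 12.9 (two-sided permutation test, p = 7e-05).

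With each gene ranked by its highest promoter summit, most of the first 15 places were shared by neighbouring genes. The summit shared by lin-35, the worm retinoblastoma gene, and vps-51 lay on chromosome I at 5807467, 242 bp upstream of lin-35, with a pooled signal of 606. The E3 ubiquitin ligase gene eel-1 had a summit 570 bp upstream with a signal of 559. A summit in a 5′ UTR, with a signal of 558, was shared by cux-7, lig-4, which encodes DNA ligase IV, and C07H6.2. The glutamyl-tRNA synthetase gene ears-2 and its neighbour uncp-18 shared a summit of 548, and the splicing factor gene prp-19, K10D2.5 and emb-1 shared one of 515. The histone demethylase gene jmjd-1.2 and F29B9.11 shared a summit of 492, Y50D4C.5 had 471, and idhg-1, for an isocitrate dehydrogenase subunit, and mlcd-1 shared 468. The remaining places were shared by Y92H12BR.2 and Y92H12BR.3 (463), wbp-4 and F56G4.6 (450.0), sup-35 and Y48A6C.4 (449.8), Y41D4A.4 and Y41D4A.6 (446), and chaf-2 and Y71G12B.30 (438).

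The tagged gene, ceh-2, had reproducible peaks in its own locus on chromosome I, 6046788 to 6050451 on the minus strand. Its intron held summits at 6047927, with a pooled signal of 380, and at 6048135, with 252. Both overlapped the same replicate peaks, with signals of 189 in replicate 1 and 191 in replicate 2. The summit at 6047927 lay 0 bp from the noncoding RNA gene C27A12.11, which was looked up after the data were seen. Whether that gene accounts for the peak was not tested. An intergenic summit lay 783 bp upstream, at 6051234, with a pooled signal of 224, and 127 and 94.8 in the replicates. The peaks of a transgenic line at the tagged gene can come from the native locus, from the transgene or from both. No reproducible summit lay in unc-119, a transgene marker in many worm lines, which held 5 relaxed summits.

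The third comparison asked whether gene groups fixed beforehand had promoter peaks more or less often than other genes. Of 19973 protein-coding genes, 1189 had a reproducible summit in the window, or 5.95%, and 5869 had a relaxed one. Ribosomal protein genes had one more often, 26 of 76, or 34.2% against 5.85% of other genes (odds ratio 8.45, 95% interval 5.26 to 13.6, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 8.28e-13). Their strongest were rps-24 (418), rpl-15 (356), rpl-3 (328) and rps-26 (284). Chemoreceptor genes, most of which act in a few sensory neurons, had one less often, 6 of 1309, or 0.458% against 6.34% (odds ratio 0.0737, exact test, adjusted p = 1.68e-26). The strongest of these were sre-23 (415), sre-1 (256), srh-89 (165) and sri-5 (157). Both calls also passed when summits were shifted within chromosomes (permutation, adjusted p = 0.0018). Among genes with a relaxed promoter summit the odds ratios were closer to 1, at 2.55 for ribosomal proteins (26 of 67) and 0.292 for chemoreceptors (6 of 92; exact tests, adjusted p = 0.0052 for both).

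The other 16 of the 18 groups did not pass the adjusted exact test. Body wall muscle genes had 4 of 22 (unc-60, unc-15, unc-89 and act-4, exact test, adjusted p = 0.0996), and epidermal collagens had 3 of 176 (col-71, col-2 and col-185, adjusted p = 0.0606). Neuropeptide genes had 2 of 140 (ins-39 and flp-23, adjusted p = 0.079) and nuclear receptors 8 of 275, led by nhr-255, nhr-142, nhr-48 and nhr-1 (exact tests, adjusted p = 0.0854). Transcription factors of the bHLH, T-box, forkhead and SOX families had 0 of 72 (exact test, adjusted p = 0.079), and homeobox genes had 3 of 99, ceh-2, ceh-38 and ceh-39 (adjusted p = 0.43). The pharyngeal cuticle group, defined only by the gene symbols abu and pqn, had 7 of 70, led by pqn-70, pqn-71, pqn-87 and pqn-42 (exact test, adjusted p = 0.364). Whether each member is a gene of the pharyngeal cuticle was not checked. Histone genes had 7 of 72, led by the pairs his-67 with his-68 and his-61 with his-62 (exact test, adjusted p = 0.364). Germline genes had 3 of 25, mex-1 (425), nos-3 and spn-4 (exact test, adjusted p = 0.364). Pan-neuronal genes had 2 of 21, ehs-1 and syd-2 (exact test, adjusted p = 0.496), hedgehog-related genes 2 of 85, wrt-3 and grl-26 (adjusted p = 0.4), and Wnt and Notch genes 1 of 23, apx-1 (adjusted p = 1). Intestinal genes had 0 of 23 (exact test, adjusted p = 0.511). Without replicate 2, body wall muscle genes had 2 of 22 and hedgehog-related genes 1 of 85, and without replicate 1 Wnt and Notch genes had 2 of 23. With either replicate alone, the bHLH, T-box, forkhead and SOX families had 1 of 72, and in the stricter set of the strongest peaks body wall muscle genes had 0 of 22. Away from tRNA, snoRNA and snRNA genes, hedgehog-related genes had 0 of 85 (exact test, adjusted p = 0.0544), so both summits named for them were near such genes, and neuropeptide genes had 1 of 140 (adjusted p = 0.0225).

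Outside the pharyngeal cuticle group, 3 groups of genes of the pharynx, where ceh-2 is known to be expressed, had no reproducible promoter summit. These were 0 of 16 genes of neurons linked to ceh-2 (exact test, adjusted p = 0.745), 0 of 10 pharyngeal muscle genes (adjusted p = 1) and 0 of 14 genes of pharynx development (adjusted p = 1). Of the 37 genes in these 3 groups together, 2.20 would have been expected at the rate of all genes, so a lower rate was not detectable (Fisher's exact test, p = 0.17). Relaxed summits lay in the windows of 12 of them, against 10.9 expected.

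**Figure D2:**
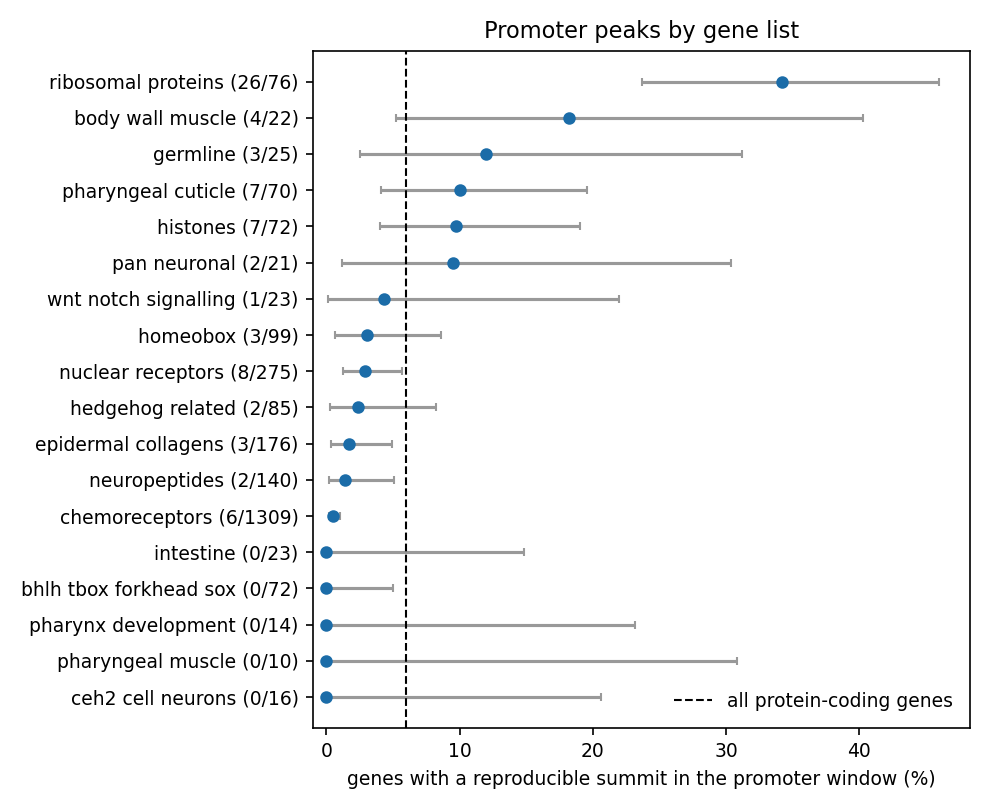
Percent of genes in each of the 18 groups with a reproducible summit in the promoter window (horizontal), with exact 95% binomial intervals as bars and members with a summit over members tested beside each name. The dashed line is the 5.95% of all protein-coding genes; ribosomal proteins lie at 34.2% and chemoreceptors at 0.458%.

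The fourth comparison asked how the peaks were spread over chromosomes. Chromosomes I and III were densest, with 18.4 and 19.01 peaks per Mb (adjusted p = 1.19e-05 and 4.48e-06 against the rest of the genome, two-sided exact binomial test). Chromosomes IV and V were sparsest, with 10.7 and 9.18 (exact test, adjusted p = 1.19e-05 and 2.44e-12), and chromosome II had 14.8 (adjusted p = 0.556). Chromosome X had 16.1, a ratio of 1.16 to the autosomes (95% interval 1.02 to 1.32, exact test, adjusted p = 0.0318). Without the peaks at tRNA, snoRNA and snRNA genes, a setting chosen after seeing the data, the X ratio was 0.993 (exact test, p = 0.97). In the stronger part of the set it was 1.11 (exact test, p = 0.278). Per protein-coding gene instead of per Mb, the X ratio was 1.57 (95% interval 1.38 to 1.79, exact test, p = 6.51e-11), and 1.35 without the peaks at tRNA, snoRNA and snRNA genes (exact test, p = 0.000138). The pooled relaxed list, which includes the reproducible peaks, held 2991 peaks on chromosome I (15.1 Mb) and 2677 on III (13.8 Mb). It held 2402 on IV (17.5 Mb) and 2473 on V (20.9 Mb). The higher density of I and III than of IV and V was thus not particular to the reproducible set.

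**Figure D3:**
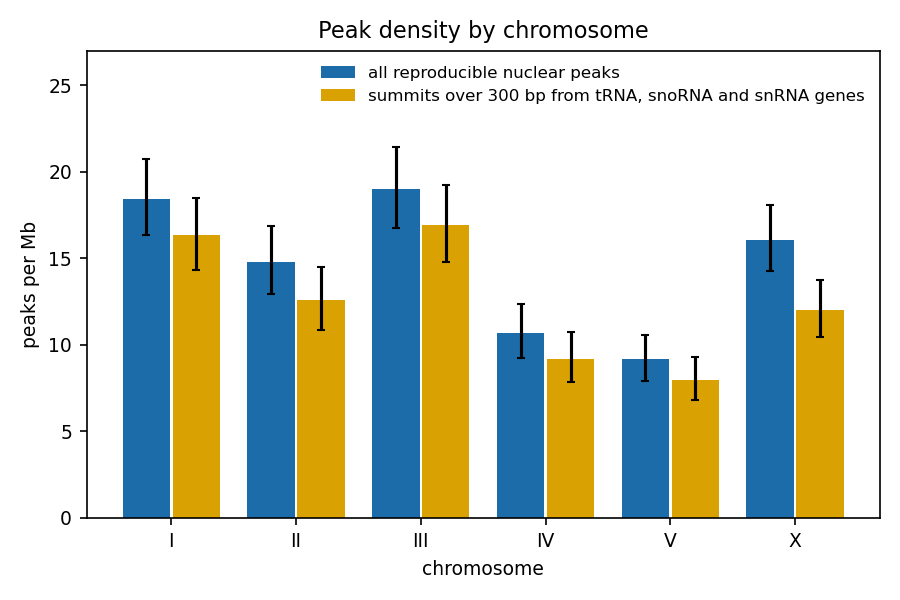
Reproducible peaks per Mb on each nuclear chromosome, for all 1430 nuclear peaks (blue) and for the 1212 with a summit over 300 bp from tRNA, snoRNA and snRNA genes (yellow), with exact 95% Poisson intervals as bars. Chromosome X falls from 16.1 to 12.02 peaks per Mb.

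The fifth comparison asked whether summits held the homeodomain core. TAATTA or TAATGA lay within 50 bp of 52 of the 1430 summits, or 3.64%, against 10.4% of windows centred 300 bp away, a ratio of 0.350 (two-sided exact McNemar test, p = 1.55e-10 for the right flank and 8.17e-15 for the left). Without replicate 1 it was 82 of 1429 summits, or 5.74%, against 11.4% of flanks. Counted from the highest ratio, TAATTA ranked 5 of the 14 6-mers of 3 A and 3 T, and 13 of those 14 passed the adjusted exact test for a lower share at summits. In the scan of all 2080 6-mers, 495 were higher at summits and 396 lower after adjustment. GAGAGA lay at 24.5% of summits and 7.45% of flanks (exact test, adjusted p = 9.87e-33), and GGCCAC at 13.99% and 1.82% (adjusted p = 4.87e-30). The median GC content was 49.5% at summits and 35.6% in the flanks. Peaks are the unit of these tests, so the p-values do not measure the spread between replicates.

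**Figure D4:**
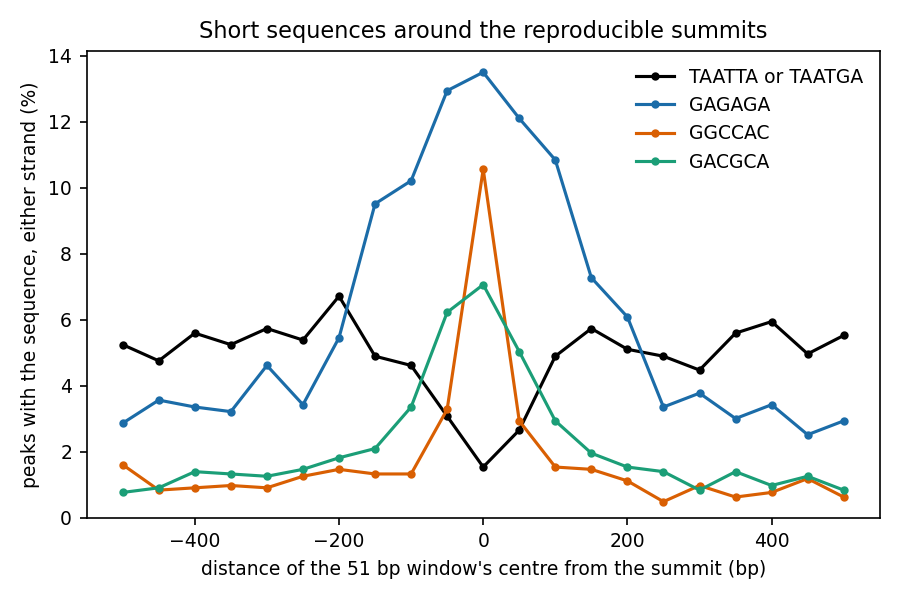
Percent of the 1430 reproducible nuclear peaks with a sequence on either strand (vertical) in windows at set distances from the summit in bp (horizontal), 1 line per sequence. Each window reached 25 bp to either side of its centre, against 50 bp in the text, so the percents differ from those given there. At the summit GAGAGA reached 13.5% and GGCCAC 10.6%, and the TAAT cores fell to 1.54% from 5.24% at 500 bp to the left.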

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

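The counts at tRNA, snoRNA and mitochondrial sequences were made only after the peaks were seen, as were the tests of TAATTA and TAATGA against other 6-mers and both transgene tests. The tests of tRNA genes of unique sequence, of cores at these genes and of GC content were written down before their results were seen.

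Reproducible summits lay within 300 bp of 150 of 612 tRNA genes and 65 of 346 snoRNA genes, a class of loci outside the protein-coding comparisons. Together with snRNA genes these loci took 218 summits, or 15.2%, and tRNA genes took 9.86% of summits against 0.397% for shifted positions (permutation by circular shift, adjusted p = 0.00028). Of the 143 tRNA genes of unique sequence, 13.99% had a summit against 0.956% for shifted positions, so the peaks were not limited to tRNA genes with identical copies. Shared reads are not excluded by this, because genes of nearly identical sequence and genes within 300 bp of a repeated one were not separated. Such reads may add to the peaks, since 27.7% of the 469 tRNA genes with a repeated sequence had a summit (Fisher's exact test, p = 0.0008). Enrichment of active chromatin without CEH-2 stays open: the core ratio at summits of tRNA, snoRNA, snRNA and ribosomal protein genes was 0.196, and no other immunoprecipitation was analysed here, so no biological explanation was tested.

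TAAT cores were rarer at summits than in flanks. The GC content was tested only between reproducible summits and relaxed peaks outside the reproducible set. Within steps of 5 percentage points of GC, the odds ratio of a core was 0.621 (95% interval 0.464 to 0.830), closer to 1 than the 0.336 without strata. GC content thus did not account for the whole difference between these sets, which also differed in location. Summits and flanks were not compared at equal GC, so the test cannot decide for that contrast. For TAATTA at summits against flanks, a shortage of A and T 6-mers may be enough: its ratio of 0.410 lay within the 0.263 to 0.583 of the other 13 6-mers. Against relaxed peaks at equal GC its odds ratio was 0.964, and those of the other 13 ran from 0.804 to 1.56 with a median of 1.12. Only 2 of these 13 were below 1, so that contrast showed no general shortage of A and T 6-mers. TAATGA, at 0.303 for summits against flanks, ranked 58 of the 60 6-mers of its base composition counted from the highest ratio, inside their central range of 0.269 to 0.753. Its odds ratio against relaxed peaks at equal GC was 0.429 (95% interval 0.278 to 0.662). That value was not set against those of the other 59 6-mers, so whether it is unusual for this base composition is unknown. What lowers TAATGA stays open, and no biological explanation was tested.

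The peaks in and upstream of ceh-2 could reflect extra copies in a transgene: relaxed summits were dense both in ceh-2, at 0.819 per kb (percentile 98.4 among genes of 2 kb or longer), and in the marker gene unc-119, at 0.794 (percentile 98.2). Extra copies of the wider neighbourhood predict more relaxed summits 2 to 10 kb to either side of ceh-2, and 0 were found there against 2.56 expected, an upper limit of 3. Extra copies limited to the gene cannot be told apart from binding, since the gene held only 3 relaxed summits, of which 33.3% lay in coding exons against 17.1% of its length (one-sided exact binomial test, p = 0.922). The control could also have removed such a signal in part, and no biological explanation was tested.

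The mitochondrial genome, outside the measurement of nuclear binding, held 23 of the 1453 reproducible peaks, or 1.67 per kb, with a median signal of 344 against 126 for nuclear peaks.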

How the results depend on the processing

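The settings without tRNA, snoRNA and snRNA loci, with mitochondrial peaks and with GC strata were chosen after seeing the data, as was the statistic of the position test. Replicate overlap, the promoter share, the signal difference and the lower share of TAAT cores kept their direction and their side of the threshold in every setting run for them. Without either replicate the promoter share was 61.0% to 62.7%, the X ratio 1.15 to 1.19, the number of gene groups called 2 in both, the core ratio 0.333 to 0.505 and the signal difference 6.67 to 7.24 on the replicates' own scale. Away from tRNA, snoRNA and snRNA genes the X ratio per Mb fell to 0.993 (95% interval 0.857 to 1.15, exact test, p = 0.97), so the call per Mb was lost with these peaks, 72 of the 285 X peaks being at tRNA genes. Per protein-coding gene the ratio was 1.57, and 1.35 without these peaks, so that call was not lost. In the stricter set of the strongest peaks the X ratio was 1.11 (exact test, p = 0.278) with fewer peaks, and the rank correlation moved to 0.763, for which the cause was not tested. The number of gene groups called moved from 2 to 4 away from these genes, adding neuropeptides and collagens, and to 5 with the 2000 bp window, adding nuclear receptors as well. All 3 were lower than other genes by the exact test, and the cause was not tested. In the main set the position test called none of the 3 (permutation by circular shift, adjusted p = 0.664 for each), and it was not run in these settings. The replaced position statistic had called 7 groups, 5 of them with no member hit, by its construction. The present one called 2. At equal GC count the core odds ratio against relaxed peaks was 0.630. The unknown read depth limits what the missing peaks of a group can show.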

Other observations

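All tests and noncoding genes named here were chosen after seeing the data.

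Of the 896 summits in promoter windows, 307 lay in windows of both strands, or 34.3%, against 8.85% for shifted positions (two-sided p = 0.002, the smallest that 1000 permutations by circular shift can give). The pairs lin-35 with vps-51 and chaf-2 with Y71G12B.30 were among them.

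Outside promoter windows, 153 of 534 summits lay within 300 bp of a tRNA, snoRNA or snRNA gene. The strongest of all 534 was in an intron at the snoRNA gene C51F7.4 on chromosome V, at 12303636, with signals of 323 and 346 in the replicates. A summit beside the snoRNA gene W03C9.9 followed, with 269 and 316. Of the tRNA genes, 80 of 276 on chromosome X and 70 of 336 on the autosomes had a summit (Fisher's exact test, p = 0.0233). Summits also lay at 16 of 261 miRNA genes, 11 of 129 snRNA genes, 9 of 194 lincRNA genes and 0 of 20 rRNA genes. The shares of summits at miRNA and snRNA genes were above those of shifted positions (permutation by circular shift, adjusted p = 0.00028 for both). The share at lincRNA genes, 0.699% against 0.362%, was not called (permutation by circular shift, adjusted p = 0.107). The largest class was that annotated only as ncRNA, with a summit within 300 bp of 443 of 7764 genes. It took 353 summits, or 24.7%, against 4.62% for shifted positions (permutation by circular shift, adjusted p = 0.00028). Of these, 204 lay outside promoter windows.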
